A study of Cricetulus griseus with 6 samples.

How the data were processed

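Gene expression was measured in single cells of 2 clonal Chinese hamster ovary lines, with 1 library for each of 3 culture states per clone. Per the labels' protocols, the cells grew in serum-free medium in shake flasks, and libraries were made with a Chromium kit that reads the 3' ends of transcripts. Per the submitters' processing notes, reads were processed with Cell Ranger 6.0.2. The genome build and annotation are not given in the sources used here, so no coordinates are printed. The deposited values are raw UMI counts, whole numbers of unique molecular identifiers (UMIs) per feature and barcode, in the filtered barcode matrix of each library. Each matrix held 20827 features, of which 4404 had no gene symbol. The last 3 features, igg_hc, igg_lc and Glul, carry no Ensembl identifier. They are read here as the antibody heavy chain, the antibody light chain and glutamine synthetase. Whether Glul counts the hamster gene, a transgene or both is not given in the sources used here.

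Cells with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 33519 of 38961 barcodes. Scrublet, as run in scanpy, called 0 to 11 doublets per library, at most 0.311% of the kept cells. That caller has therefore not worked on these data, and doublets stay among the kept cells. Depth over kept cells ran from 98271351 UMIs in clone A at passage 30 without glutamine to 226722925 in clone B in the same state. For shares of cells, phases, clusters and variable genes, each cell was thinned at random to 2000 UMIs, the 10th percentile of the shallowest library rounded down to a multiple of 500. This left out 506, 296 and 55 cells of clone A (passage 0, passage 30 with glutamine, passage 30 without) and 54, 69 and 136 cells of clone B in the same order.

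For tests, counts were summed over the kept cells of each library. edgeR's quasi-likelihood F test was fitted to all 6 libraries with clone and culture state as terms, TMM scaling and edgeR's default low-count filter, which left 11467 genes and 2 residual degrees of freedom. Each culture comparison thus has the clones as its repeated unit. The clone comparison has the culture states as blocks and speaks of these 2 clones alone. The labels do not say whether libraries of one clone came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Gene lists were tested with camera in limma with a preset correlation of 0.01 on log2 CPM (UMI counts scaled to a common, TMM-adjusted library total), and again with an estimated correlation and with fry. Of 35 lists, 31 were tested, 3 held markers of other cell types, and 1 list of RNA quality transcripts had 0 of its 7 members in the matrix. For each clone alone, log2 folds are of CPM + 1, and a list's median was set beside 10000 random lists of the same size matched on mean expression. A median of such random lists is printed below only for ribosomal proteins. Camera does not match on expression, so other list calls may in part follow expression level.

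The named genes follow a fixed rule. Per culture comparison it takes the 8 genes higher and the 8 lower in both clones with the largest value of the smaller absolute log2 fold, among genes with a symbol and a mean of at least 10 CPM. It adds the 3 genes higher in clone A and lower in clone B, and the 3 the other way round. For the clones it takes 8 genes each way with the same sign in all 3 culture states. Each list passing camera adds 3 members, not all of which are printed, and igg_hc, igg_lc and Glul are always named. Genes that pass within a single list, and genes named for varying most between cells, were named after their values were seen. The groups, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. The classes of cells with few heavy chain UMIs, every test on them and the checks at 10000 UMIs were chosen after seeing the data.

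Phases were scored with the S and G2/M lists in scanpy. Cells of each clone were clustered on 2000 variable genes without cell cycle genes, 30 principal components, 15 neighbours and a Leiden resolution of 0.5. A cluster was to be named only with at least 3 markers of a fixed list among its 10 leading genes. Only some of the lists were checked for this, and the extracellular matrix list was not among them. Variable genes were ranked by the squared coefficient of variation beyond counting noise, among genes with a mean of at least 0.1 UMI per thinned cell. Alternatives covered DESeq2, other scalings, other filters on genes and cells, thinned cells, cells called G1, the model without its block, and each library left out in turn. Where 1 library is left out, the other library of its state is fitted by its own state term. Leaving out either passage 0 library therefore gives nearly the same fit for glutamine and for the clones, on the passage 30 libraries. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9.

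Some steps were tested on simulated data with known changes, namely edgeR, DESeq2 in 2 of the 4 comparisons, camera, thinning, the variation beyond counting, the random lists and the edgeR fit of the heavy-chain-low class. Clustering, phase scoring, fry and the matching on cluster were not. At the spread measured here, a biological coefficient of variation of 0.2051, edgeR recovered all 100 simulated 4-fold changes in every comparison. The simulation gave every gene that same spread and each change the same size in all libraries of a group. A lack of calls in the data therefore does not exclude 4-fold changes. Of the 100 simulated 2-fold changes it recovered 32 for passage 30 without glutamine against passage 0, 51 for glutamine at passage 30, 43 for passage 30 with glutamine against passage 0, and 75 for the clones. DESeq2 recovered 52 in the first of these and 84 in the last. With 17 and 24 false calls there, against 7 and 9 for edgeR, DESeq2 counts are the looser of the pair. A simulated list shifted by 0.5 passed camera with an adjusted p of 4.27e-11, and with an estimated correlation its adjusted p was 0.467, so the estimated correlation had little power for such a list. Its members varied independently, so the preset of 0.01 was not tested for correlated lists. The estimate in the data was 0.71 for ribosomal proteins and 0.39 for the amino acid response, but −0.05 for mitochondrially encoded transcripts. Where it is high, camera calls with the preset may be too many. Of simulated lists with no shift, 13.0% fell outside the 5th to 95th percentile of their random lists.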

Results

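Chinese hamster ovary (CHO) cells are a common host for producing antibodies. Clones A and B of the CHO K1GS line, both with antibody heavy and light chain transcripts, were profiled by single-cell RNA sequencing at the start of a long culture without glutamine (passage 0) and at passage 30, with 6 mM glutamine or without it. The labels describe the length of the culture both as 30 passages and as 30 population doublings. The series set out to follow subpopulations of cells inside clonal lines. The 6 libraries form 6 groups of 1 library each. Kept cells numbered 5428, 3536 and 5344 for clone A at passage 0, passage 30 without and passage 30 with glutamine, and 5091, 6831 and 7289 for clone B. Their median depth lay between 22730 and 29790 UMIs per cell. Values of a single library have no replicate check, and their 95% intervals (Poisson for levels, exact binomial for shares) cover counting error only.

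Antibody transcripts were lower at passage 30 than at passage 0 in both clones. Heavy chain RNA stood at 6149 CPM (6135 to 6162) in clone A at passage 0, 5031 CPM (5017 to 5045) at passage 30 without glutamine and 2991 CPM (2983 to 3000) with it. In clone B the heavy chain levels were 4285 CPM (4275 to 4295), 2489 CPM (2483 to 2496) and 2263 CPM (2257 to 2270). Light chain RNA went from 13764 CPM at passage 0 to 12606 without and 7391 with glutamine in clone A, and from 17047 to 8701 and 10672 CPM in clone B. Glul, which encodes the enzyme that makes glutamine from glutamate, stood at 25.2 CPM (24.3 to 26.1), 24.3 CPM (23.4 to 25.3) and 18.2 CPM (17.5 to 18.8) in clone A, and at 48.0 CPM (46.9 to 49.0), 29.5 CPM (28.7 to 30.2) and 29.2 CPM (28.4 to 29.9) in clone B. Across the clones, edgeR put passage 30 with glutamine against passage 0 at a log2 fold of −0.98 ± 0.20 (SE) for the heavy chain, −0.77 ± 0.29 for the light chain and −0.60 ± 0.19 for Glul, each with an adjusted p of 0.694.

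The share of cells almost without heavy chain RNA was higher at passage 30 than at passage 0 in both clones. After thinning to 2000 UMIs, 0.366% of clone A cells had no heavy chain UMI at passage 0, 2.36% at passage 30 without glutamine and 9.45% with it. In clone B these shares were 6.81%, 44.2% and 24.7%. Before thinning they were 0.0368%, 0.481% and 2.13% in clone A and 0.236%, 15.9% and 7.49% in clone B. With a class of at most 4 heavy chain UMIs of 10000, called heavy-chain-low here and set after seeing the data, clone A held 0.237% (0.118 to 0.423) at passage 0, 1.68% (1.27 to 2.17) without glutamine and 8.93% (8.15 to 9.76) with it. Clone B held 6.37% (5.70 to 7.09), 47.1% (45.9 to 48.3) and 26.3% (25.3 to 27.3). The glutamine-fed culture thus had the larger share in clone A and the smaller in clone B, with 1 library each and no test of the difference. The class is a range on a scale, and cells with 3 to 7 heavy chain UMIs made up 8.34% of the clone B passage 0 cells, 1.71% to 4.43% of those at passage 30 and 6.57% of clone A cells at passage 30 with glutamine.

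Many of these cells kept some light chain RNA, though less than the others. In clone B at passage 30 without glutamine, the median light chain count was 26 UMIs per 10000 in heavy-chain-low cells and 113 in the others. These medians were 18 and 115 in clone B with glutamine, 18 and 144 in clone B at passage 0, and 6 and 79 in clone A with glutamine. Heavy-chain-low cells above the light chain limit of 8 UMIs were 29.0% of clone B cells at passage 30 without glutamine, 14.7% with it and 5.07% at passage 0, and 4.26% of clone A cells at passage 30 with glutamine. The reverse, few light chain UMIs with the heavy chain kept, was seen in 0.108% to 0.632% of cells. Over kept cells, light chain UMIs outnumbered heavy chain UMIs by 2.24 to 1 up to 4.72 to 1. Limits of 4 and 8 UMIs can therefore favour the first of these classes, and by how much was not tested. With limits of 2 and 5, and of 8 and 12, it held 29.0% and 29.6% of clone B cells at passage 30 without glutamine. These shares were 14.2% and 17.55% in clone B with glutamine, 2.88% and 10.8% in clone B at passage 0, and 2.67% and 9.07% in clone A with glutamine. The class thus depended on the limits most in clone B at passage 0 and clone A with glutamine. Free RNA can reach every droplet, and the libraries hold no cell type that should lack the antibody. Barcodes under 1000 UMIs, used as a stand-in for such a type, held 17.7 to 45.3 heavy chain UMIs per 10000. The median heavy-chain-low cell of clone B held 0 at passage 30. These barcodes come from the filtered matrix, and their content does not measure the free RNA added to a deep cell. The class was defined by few heavy chain UMIs, so its low count and its high ratio of light to heavy chain follow in part from that choice. Light chain UMIs outnumbered heavy chain UMIs by 80.4 to 1 in heavy-chain-low cells of clone B without glutamine and by 60.3 to 1 with it, against 4.36 and 5.69 in barcodes under 1000 UMIs and 2.88 and 4.34 in the other cells. In clone B at passage 0 the ratio was 9.22 in heavy-chain-low cells and 5.17 in barcodes under 1000 UMIs, and in clone A with glutamine 12.9 and 3.13. Free RNA could supply part of the light chain in these cells, and how much was not measured in any library. Glul stood at 0.261 UMIs per 10000 (0.208 to 0.324) in heavy-chain-low cells of clone B at passage 0 and at 0.518 (0.498 to 0.539) in the others. At passage 30 the Glul intervals of the classes overlapped in clone B, at 0.273 (0.255 to 0.292) and 0.258 (0.241 to 0.275) without glutamine and 0.277 (0.254 to 0.302) and 0.292 (0.278 to 0.307) with it.

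**Figure D1:**
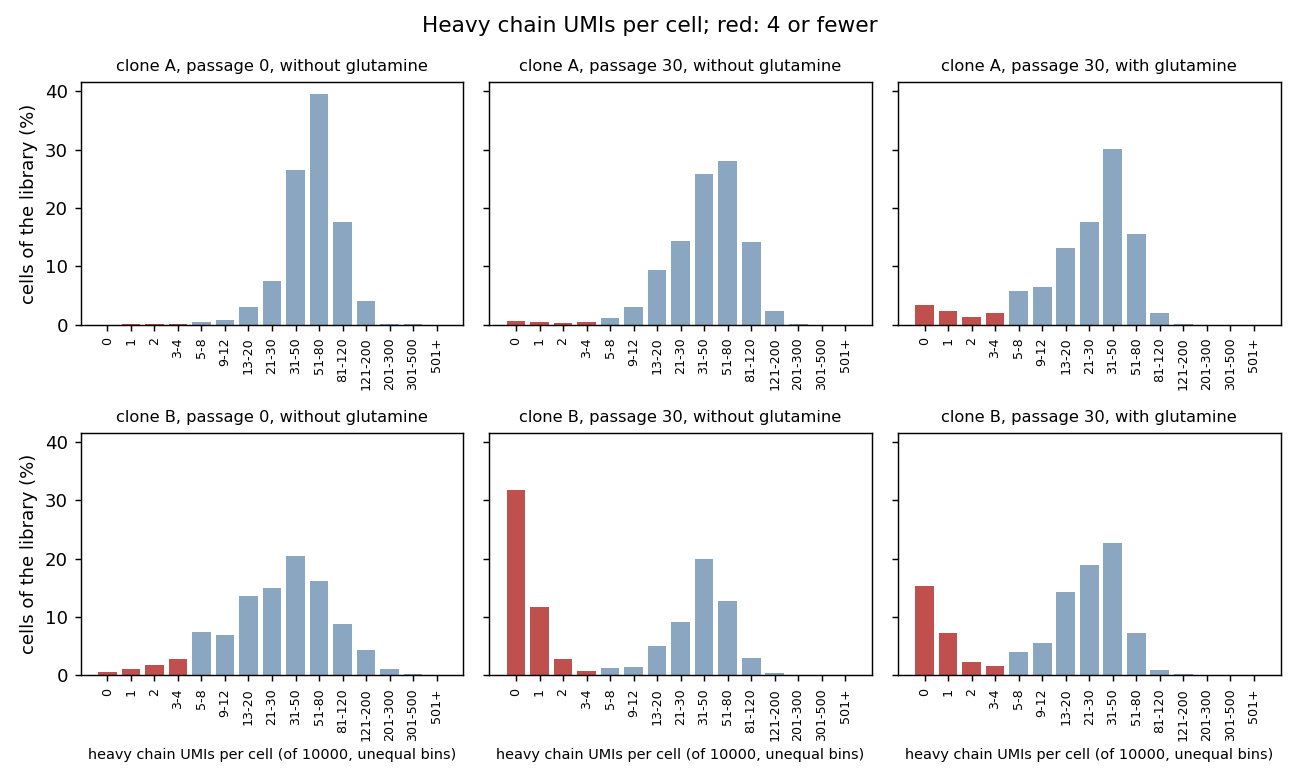
Distribution of heavy chain UMIs per cell in each of the 6 libraries, each cell thinned to 10000 UMIs (x axis, UMIs; y axis, percent of cells). The clone B libraries at passage 30 hold a group of cells at or near 0 heavy chain UMIs, 47.1% of cells at 4 UMIs or fewer without glutamine and 26.3% with it.

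Passage 30 without glutamine against passage 0 addresses the long culture in unchanged medium. Of 5809 genes with a symbol and a mean of at least 10 CPM, 2565 (44.2%) had the same sign in both clones. The genes named below are the extremes of a ranking and do not show that the clones changed alike. The share with the same sign was 64.1% (3707 of 5785) for glutamine at passage 30 and 51.7% (3003 of 5813) for passage 30 with glutamine against passage 0. Slpi, a secreted inhibitor of serine proteases, was higher in both clones, with log2 folds of 1.71 in clone A and 2.45 in clone B (6.38 to 23.1 CPM and 5.85 to 36.4 CPM). At such low levels the size of its folds rests in part on the pseudocount. Among the 8 genes named as higher in both clones were also complement component C3 (0.89 and 3.11), the chemoattractant precursor Rarres2 (1.94 and 0.99), C1qtnf1 (1.07 and 4.28) and the nuclease Dnase1l3 (0.82 and 1.61). Lmo2 (1.10 and 1.21), Anxa1 (0.95 and 1.11) and the p53-responsive kinase Plk2 (0.90 and 1.00) completed these genes. Lower in both were the flippase Atp10a (−0.95 and −2.13), the caveolar coat gene Cavin4 (−0.88 and −3.00), the aminoacylase Acy3 (−1.10 and −1.42), Mtss1 (−1.08 and −0.94), the mesenchymal transcription factor Snai2 (−1.18 and −0.64), the adhesion molecule Alcam (−0.72 and −0.68), Dixdc1 (−0.62 and −0.68) and the vitamin D receptor Vdr (−0.60 and −0.62).

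Some genes went opposite ways in the clones. Smooth muscle actin Acta2 had log2 folds of 2.16 in clone A and −1.11 in clone B, cyclin D1 (Ccnd1) 1.47 and −1.44, and the actin regulator Evl 1.11 and −1.45. The transferrin receptor Tfrc went the other way, at −0.98 and 1.52, as did the interferon-induced Mx2 (−1.06 and 1.54) and Extl1 (−0.88 and 2.64). Extracellular matrix genes had a median log2 fold of 0.23 in clone A and −1.11 in clone B, a difference that was not tested. Across the clones this list did not pass camera (adjusted p = 0.0957, and 0.988 with an estimated correlation). Heavy chain folds were −0.29 and −0.78, light chain folds −0.13 and −0.97, and Glul folds −0.05 and −0.68.

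Of the 31 lists, 3 passed camera, all with higher values at passage 30. The ribosomal protein list had 28 of 31 members higher, a median of 0.24 and an adjusted p of 5.62e-05, with an adjusted p = 0.988 with an estimated correlation. Its median was 0.43 in clone B, where lists matched on expression had 0.42, and 0.005 in clone A, and without the clone B passage 0 library the median was 0.00 with its direction in camera turned. The call was also lost without clone B at passage 30 without glutamine (median 0.12). Rpl22l1 (0.003 and 1.31) and Rpl23a (0.01 and 0.88) were among those with the largest mean folds. The amino acid response list, genes linked to the stress factor ATF4, had 23 of 28 members higher, a median of 0.19 and an adjusted p of 0.00297 (adjusted p = 0.988 with an estimated correlation). Its members with the largest mean folds in absolute size were Ddit4, an inhibitor of growth signalling (0.14 and 1.72, but −0.89 in clone A in G1 cells), the cysteinyl-tRNA synthetase gene Cars (0.35 and 0.81) and, against the direction of the list, Nupr1 (0.40 and −1.61). Proteasome subunits had 27 of 28 members higher, a median of 0.13 and an adjusted p of 0.0045 (adjusted p = 0.988 with an estimated correlation), with Psmd14 at 0.09 and 0.69, Psmb5 at 0.00 and 0.68, and Psmc6 at −0.09 and 0.71. Both of these calls were lost without clone B at passage 0 (medians 0.19 and 0.01) and without clone B at passage 30 without glutamine (0.05 and 0.11), and the amino acid response call also without clone A at passage 0 (0.30). In clone B, the median fold over genes rose with expression level in this comparison. It was −0.006 with a mean of at least 1 CPM and 0.16 with at least 100 CPM. In clone A these medians were −0.002 and −0.007. How far the amino acid response and proteasome calls follow expression level is not shown here. Single genes did not pass. edgeR called 0 of 11467 genes, with 590 at an unadjusted p under 0.05 and a smallest adjusted p of 0.735 (Slc1a3), and DESeq2 called 44 (21 higher, 23 lower). Adjusted over the list alone, Plk2 passed among p53 targets (0.00783) and Il6 among senescence genes (0.00987). These values were not adjusted over the 31 lists searched, so such passes may arise by chance. Without the clone A passage 0 library, so that clone B alone gave the passage 0 level, edgeR called 1810 genes, and it called 14 without clone A at passage 30 without glutamine, 2 without clone B at passage 0 and 1 without clone B at passage 30 without glutamine. Leaving out clone A at passage 0 or at passage 30 without glutamine gave 5 and 7 lists.

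**Figure D2:**
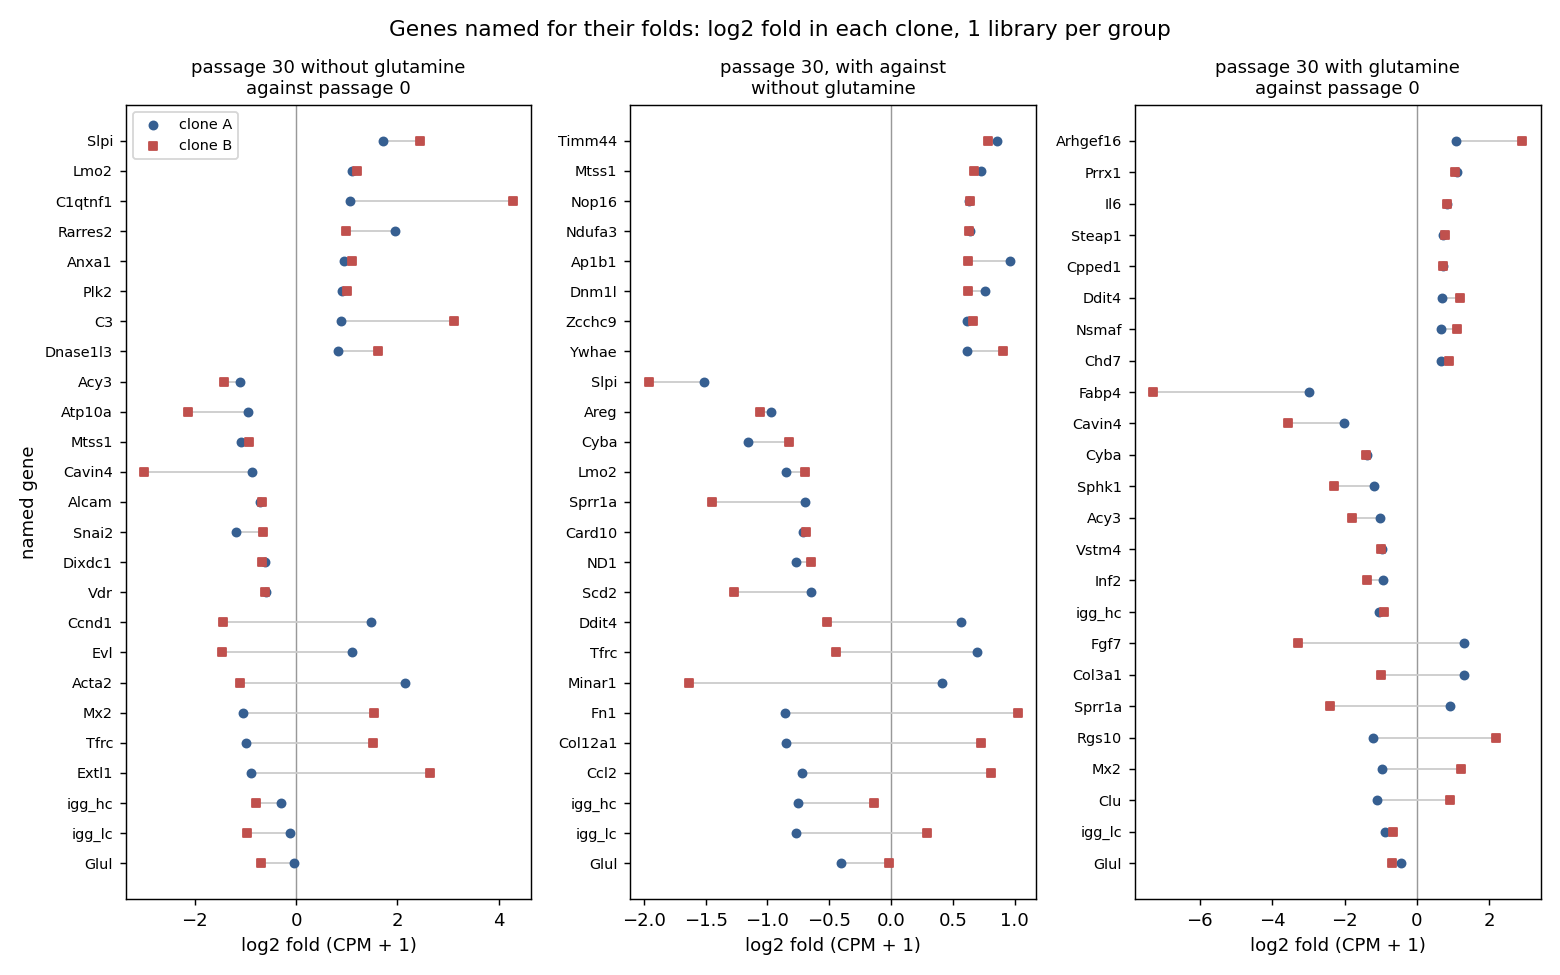
Log2 folds of CPM + 1 (x axis) for the genes named for their folds and the product and Glul features (y axis) in clone A (circles) and clone B (squares), in the 3 culture comparisons, with 1 library per group and a grey line joining the clones. Slpi lies at 1.71 and 2.45 in the first panel and at −1.52 and −1.96 in the second, and Fabp4 at −2.97 and −7.29 in the third.

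Glutamine supply at passage 30 was compared within each clone between cultures of the same passage. Mitochondrially encoded transcripts were lower with glutamine in both clones, 12 of 13 in each, with medians of −0.25 in clone A and −0.39 in clone B. ND1, a complex I subunit, stood at 6984 CPM with and 11888 CPM without glutamine in clone A and at 7706 and 12082 CPM in clone B (log2 folds −0.77 and −0.65), and ND2 (−0.77 and −0.55) and ND6 (−0.31 and −0.75) lay below 0 too. The median mitochondrial share of UMIs per cell was 8.26% with and 9.30% without glutamine in clone A and 6.32% and 7.92% in clone B. Slpi was lower with glutamine (−1.52 and −1.96), as were the EGF receptor ligand Areg (−0.97 and −1.06), the NADPH oxidase subunit Cyba (−1.16 and −0.83), Lmo2 (−0.85 and −0.70), Sprr1a (−0.69 and −1.45), Card10 (−0.71 and −0.69) and the fatty acid desaturase Scd2 (−0.65 and −1.27). Higher with glutamine were the mitochondrial import factor Timm44 (0.86 and 0.79), the fission factor Dnm1l (0.76 and 0.62) and the complex I subunit Ndufa3 (0.64 and 0.63), unlike most respiratory chain genes. Mtss1 (0.73 and 0.67), the nucleolar Nop16 (0.63 and 0.64), the clathrin adaptor Ap1b1 (0.96 and 0.63), Zcchc9 (0.61 and 0.66) and the 14-3-3 gene Ywhae (0.61 and 0.91) completed the genes named as higher in both clones.

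For glutamine, too, some genes went opposite ways. Fibronectin (Fn1) had log2 folds of −0.86 in clone A and 1.02 in clone B, Col12a1 −0.85 and 0.73, and the chemokine Ccl2 −0.72 and 0.81. Ddit4 (0.56 and −0.52), Tfrc (0.69 and −0.44) and Minar1 (0.42 and −1.64) were higher in clone A and lower in clone B. The heavy chain stood at −0.75 and −0.14, the light chain at −0.77 and 0.29, and Glul at −0.40 and −0.02. In G1 cells the heavy chain (igg_hc) in clone B stood at 0.03 and Glul in clone A at 0.01. Both values lie near 0, and the counting error of the smaller G1 sums was not computed, so no reversal is read from them. As a list, enzymes and carriers of glutamine and glutamate did not pass, with a median of −0.01 and an adjusted p of 0.818, 9 of 20 members being higher.

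Camera called 4 lists, all lower with glutamine. In G1 cells 2 lists passed as lower and 1 as higher, and in thinned cells 3 passed as lower, so calls were lost in both. Mitochondrially encoded transcripts had a median of −0.34 across clones and an adjusted p of 1.87e-06 (adjusted p = 0.729 with an estimated correlation). Nuclear genes of the respiratory chain had 29 of 35 members lower, a median of −0.14 and an adjusted p of 0.0019 (adjusted p = 0.729 with an estimated correlation), with Cox8a at −0.69 and −0.64 and Uqcrc2 at −0.12 and −0.80. Antioxidant genes had 19 of 25 members lower, a median of −0.21 and an adjusted p of 0.00993 (adjusted p = 0.873 with an estimated correlation), with Gstp1 at −0.41 and −0.90, Gpx1 at −0.50 and −0.74, and the metallothionein MT1 higher at 0.70 and 0.53. Proteasome subunits had 22 of 28 members lower and an adjusted p of 0.0494 (adjusted p = 0.873 with an estimated correlation), with Psma1 at −0.29 and −0.30, Psma3 at −0.35 and −0.22 and Psmb2 at −0.29 and −0.21. edgeR called 0 of 11467 genes, with 445 at an unadjusted p under 0.05 and a smallest adjusted p of 0.984, while DESeq2 called 20 (4 higher, 16 lower). Adjusted over the list alone, ND1 and ND2 passed among mitochondrial transcripts (smallest 0.0415). Without clone A or clone B at passage 0 edgeR called 10 and 17 genes, and without clone A at passage 30 without glutamine camera called 8 lists. Without clone B at passage 30 without glutamine the antioxidant median was −0.02 with its direction in camera turned, and the calls of the respiratory chain (−0.11) and the proteasome (−0.02) were lost. Those 2 calls were also lost without clone A at passage 30 with glutamine (−0.10 and −0.04), and those of the antioxidant genes (−0.21) and the proteasome (−0.15) without clone B at passage 30 with glutamine. The mitochondrial call held whichever library was left out, with medians of −0.39 to −0.19. Leaving out a passage 0 library could not test this call, since the glutamine comparison then rests on the same passage 30 libraries.

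Passage 30 with glutamine against passage 0 combines long culture and the added nutrient. Each pair of the 3 culture comparisons shares libraries, so a gene such as Slpi, Plk2, Il6, Cavin4 or ND1 that appears in more than one of them is not independent evidence. Fabp4, a fatty acid binding protein, was lower in both clones, from 82.5 to 9.64 CPM in clone A and from 778 to 3.99 CPM in clone B (log2 folds −2.97 and −7.29). Cavin4 (−2.0 and −3.55), the sphingosine kinase Sphk1 (−1.18 and −2.30), Cyba (−1.39 and −1.40), Acy3 (−1.03 and −1.81), the formin Inf2 (−0.93 and −1.37), Vstm4 (−0.97 and −0.99) and the antibody heavy chain (−1.04 and −0.92) were the other genes lowest in both. The light chain lay at −0.90 and −0.68 and Glul at −0.45 and −0.70. Higher in both were the guanine nucleotide exchange factor Arhgef16 (1.06 and 2.90), the mesenchymal transcription factor Prrx1 (1.12 and 1.05), the cytokine Il6 (0.84 and 0.83), Ddit4 (0.70 and 1.20, but −0.17 in clone A in G1 cells), Nsmaf (0.67 and 1.09), the chromatin remodeller Chd7 (0.67 and 0.88), Steap1 (0.72 and 0.79) and Cpped1 (0.71 and 0.71). The growth factor gene Fgf7 (1.31 and −3.29), Col3a1 (1.31 and −1.01) and Sprr1a (0.90 and −2.41) were higher in clone A and lower in clone B, and Rgs10 (−1.23 and 2.19), Mx2 (−0.96 and 1.21) and the chaperone Clu (−1.09 and 0.90) the reverse.

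Chaperones of the endoplasmic reticulum (ER), where antibody chains fold, were lower and sterol synthesis genes higher. The ER list had 20 of 24 members lower, a median of −0.24 and an adjusted p of 0.00531 (adjusted p = 0.960 with an estimated correlation), with medians of −0.15 in clone A and −0.27 in clone B. Creld2 (−0.81 and −0.73), DNAJB9 (−0.35 and −0.66) and Manf (−0.04 and −0.95) led it. Sterol synthesis genes had 21 of 23 members higher, a median of 0.24 and an adjusted p of 0.000741 (adjusted p = 0.960 with an estimated correlation), with medians of 0.36 in clone A and 0.07 in clone B and Hmgcs1 (0.69 and 0.17), Mvd (0.54 and 0.41) and Dhcr7 (0.21 and 0.92) as examples. Mitochondrial transcripts had 12 of 13 members lower, a median of −0.28 and an adjusted p of 0.000345 (adjusted p = 0.960 with an estimated correlation), with ND1 at −0.65 and −0.59, ND2 at −0.78 and −0.56 and ND6 at −0.64 and −0.45. Markers of G2 and M phase had 38 of 50 members higher, a median of 0.16 and an adjusted p of 0.00219 (adjusted p = 0.960 with an estimated correlation), among them Ect2 (0.52 and 0.42), Rangap1 (0.40 and 0.32) and Kif20b (−0.12 and 1.15, but 0.25 in clone A in G1 cells). The calls of the ER list (−0.09) and of G2 and M phase (0.08) were lost without clone B at passage 0, that of the ER list also without clone A at passage 30 with glutamine (−0.14), that of G2 and M phase without clone B at passage 30 with glutamine (0.13), and that of sterol synthesis without clone A at passage 0 (0.10). edgeR called 0 of 11467 genes, with 775 at an unadjusted p under 0.05 and a smallest adjusted p of 0.301, while DESeq2 called 94 (18 higher, 76 lower). Adjusted over the list alone, ND1 and ND2 (smallest 0.0484), Plk2 (0.0348), Cxcl1 and Il6 (smallest 0.010) passed in their lists. Without clone A at passage 0 edgeR called 2169 genes, and it called 23 without clone B at passage 0, 17 without clone A and 17 without clone B at passage 30 without glutamine.

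Clone A was compared with clone B over the 3 culture states. Higher in clone A at passage 0, passage 30 without and passage 30 with glutamine were the nuclear envelope gene Syne4 (log2 differences of 2.93, 4.09 and 4.67), Prrx1 (1.86, 1.54 and 1.92), the pantetheinase Vnn1 (1.62, 1.35 and 2.32), Acy3 (1.38, 1.70 and 2.16) and Cited1 (2.58, 1.04 and 1.19). The glutamate and aspartate transporter Slc1a3 (1.00, 1.17 and 1.16), the tyrosine breakdown enzyme Fah (1.22, 1.09 and 0.97) and the proprotein convertase Furin (1.32, 0.97 and 1.08) were higher in clone A as well. Atp10a led those higher in clone B (−4.23, −3.06 and −3.17), followed by lumican (Lum) at −2.70, −4.81 and −6.35. The sizes for Lum and Syne4 rest on levels near 0 in one clone and on the pseudocount, Lum at passage 30 with glutamine running from −8.95 with 0.1 to −3.26 with 10. The laminin chain Lama2 (−1.67, −1.41 and −2.26), the receptor Nrp2 (−0.92, −1.53 and −1.17), the transcription factor Snai2 (−1.05, −1.59 and −2.02), Ybx3 (−1.08, −1.22 and −1.10), Gask1b (−1.75, −1.27 and −0.91) and Adh5 (−0.96, −0.91 and −1.03) made up the rest. The extracellular matrix list as a whole did not pass (median −0.57, adjusted p = 0.0550). The heavy chain was higher in clone A (0.52, 1.01 and 0.40), Glul was lower (−0.90, −0.27 and −0.66), and the light chain changed sign (−0.31, 0.53 and −0.53).

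Fatty acid synthesis genes were higher and proteasome subunits lower in clone A. The former had 12 of 13 members higher, a median of 0.35 and an adjusted p of 0.0234 by camera (adjusted p = 0.953 with an estimated correlation) and 0.0143 by fry, with Acss2 at 0.48, 0.71 and 0.67, Acaca at 0.17, 0.69 and 0.56, and Scd2 at −1.30, 1.47 and 2.09. Its camera call was lost without either passage 0 library and without either passage 30 library grown without glutamine, with medians of 0.29 to 0.39. In thinned cells it was lost too, as the 1 list that passed there was lower in clone A. Proteasome subunits had 26 of 28 members lower, a median of −0.28 and an adjusted p of 1.25e-05 by camera (adjusted p = 0.953 with an estimated correlation), but did not pass fry (adjusted p = 0.192), with Psmd4 at −0.56, −0.86 and −0.69, Psmd7 at −0.59, −0.78 and −0.58 and Psmc2 at −0.27, −0.67 and −0.75. edgeR called 0 of 11467 genes, although 2418 had an unadjusted p under 0.05 and the smallest adjusted p, shared by Atp10a and 2 more genes, was 0.0503, while DESeq2 called 1080 (474 higher in clone A, 606 lower). Adjusted over the list alone, 7 of 20 glutamine use genes passed (Pfas, Psat1, Oat, Got2, Got1, Aldh18a1 and Glul, smallest 0.0225), as did 6 of 13 fatty acid synthesis genes (Acss2, SREBF1, Me1, Fads1, Fasn and Acaca), 6 of 25 antioxidant genes (among them Cat, Gclc and Sod1), 5 of 28 proteasome subunits and 3 of 23 matrix genes (Col5a2, Lum and Col6a1). The count rested on single libraries, with 3405 genes without clone B at passage 0, 3315 without clone A at passage 0, and 115 and 101 without clone B and clone A at passage 30 without glutamine.

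The folds of the clones correlated more for glutamine than for either comparison with passage 0. Across genes, which are not independent replicates, the log2 folds of clone A and clone B correlated with Pearson's r of 0.43 for glutamine at passage 30 (Spearman's rho 0.43, 6431 genes), −0.13 for passage 30 without glutamine against passage 0 (rho −0.16, 6449 genes) and 0.13 for passage 30 with glutamine against passage 0 (rho 0.07, 6460 genes). Folds against passage 0 were wider in clone B, with 268 genes over 2-fold without glutamine and 209 with it, against 27 and 31 in clone A. Each comparison with passage 0 uses the clone B passage 0 library. That library lay 0.482 and 0.505 from the clone B passage 30 libraries (SD of log2 folds over genes). The low correlations and the wide folds may come from that library alone, so no contrast of long culture with glutamine is read from them. With or without glutamine at passage 30, 16 genes in clone A and 18 in clone B differed by over 2-fold. Scaling by library totals in place of TMM moved the median log2 fold of clone B for passage 30 without glutamine against passage 0 from 0.05 to −0.14, and the named folds that changed sign with it lay near 0, those of Rpl22l1, Rpl23a and Psmb5 in clone A in that comparison, Manf in clone A for passage 30 with glutamine against passage 0 and Glul in clone B for glutamine. Counting error on these folds was small, with a half-width under 0.2 for 66 of 68, 71 of 72 and 70 of 72 named folds in the 3 culture comparisons and 68 of 75 between the clones, where Lum had the widest (1.07).

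The genes that varied most between cells differed between libraries. C3, Fabp4, Nupr1 and Thbs1 led clone A at passage 0, with a squared coefficient of variation beyond counting of 5.69 for C3. The chemokine Ccl2 led clone A at passage 30 with (32.1) and without glutamine (19.8) and clone B without it (16.9). With strict cells Ccl2 was not among the first 5 in either clone A library, nor with cells not thinned in the one with glutamine, where its mean of 0.101 UMI lay at the lower limit. In clone B, Extl1 stood at 14.0 and 13.9 at passage 30 with and without glutamine, and Nppb (21.9), Rnd3, Cited1, Arl6ip6 and S100a4 led at passage 0. Fn1 in clone A and Txnip and Cited1 in clone B were among the first 5 without glutamine at passage 30. The heavy chain ranked 449, 254 and 104 in clone A and 33, 19 and 34 in clone B at passage 0, passage 30 without and passage 30 with glutamine.

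Clustering gave 4 clusters in each clone, none with 3 markers of a list checked for naming, so all stayed unnamed. They were not stable, since another random seed gave 5 clusters in clone A and 4 in clone B, with an adjusted Rand index of 0.559 and 0.484 to the clusters used here. The largest cluster of clone B then held 70.8% of cells in place of 39.5%. In clone A, cluster 3 of this clustering held 8.0% (7.27 to 8.79) of cells at passage 30 with glutamine against 0.163% at passage 0 and 0.345% without glutamine, and 23.5% of its glutamine-fed cells were heavy-chain-low. Its leading genes included Col4a1, Fn1 and Col5a1, but the extracellular matrix list was not checked for naming. In clone B, cluster 0 held 99.2% of passage 0 cells and at most 0.0416% of cells at passage 30, so that it cannot be told from that library. Phase scoring put 70.9% to 80.2% of cells in G2 or M phase in every library, and no cycling is read from these calls. S phase markers did not pass camera in any comparison, with medians of −0.07 (clones) to −0.02. Markers of blood cells, endothelium and nerve were near absent, with Ptprc at up to 0.0182 CPM and Map2 at up to 0.102 CPM, and of 8 epithelial markers only Krt7 passed 10 CPM (12.5 CPM).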

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

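The tests of the 3 patterns weighed here were chosen after the results were seen.

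Some genes moved in opposite directions in the clones, and these differences were not tested, since each clone has 1 library per state. For passage 30 without glutamine against passage 0, the log2 fold of clone A minus that of clone B was 3.27 for Acta2, 2.91 for Ccnd1, 2.57 for Evl, 2.01 for Nupr1, −0.80 for Psmc6, −2.50 for Tfrc, −2.60 for Mx2 and −3.52 for Extl1. For glutamine at passage 30 it was 2.05 for Minar1, 1.14 for Tfrc, 1.08 for Ddit4, −1.06 for the antibody light chain igg_lc, −1.53 for Ccl2, −1.58 for Col12a1 and −1.88 for Fn1. For passage 30 with glutamine against passage 0 it was 4.60 for Fgf7, 3.31 for Sprr1a, 2.32 for Col3a1, −1.28 for Kif20b, −2.0 for Clu, −2.17 for Mx2 and −3.42 for Rgs10. The share of heavy-chain-low cells was higher with glutamine in clone A and lower in clone B, and the difference of those differences was 28.1 points, also not tested.

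Cells with little heavy chain RNA were the first pattern weighed. The heavy-chain-low class was set after each cell was thinned to the same UMI total, with shallower cells left out. UMI totals before thinning therefore cannot test shallow sequencing as a cause, and no conclusion is drawn from them. The median total of heavy-chain-low cells was at least 0.949 of that of the other cells in the 4 libraries with at least 100 such cells. Cells of a line as distant as the other clone are argued against as the whole class. The largest SD over genes of the log2 folds of the class against the other cells was 0.140, with 0.421 between the clones in the same state. A part of the class from such a line, or a more closely related line, is not excluded. Loss of heavy chain expression with length of culture may contribute, as the share was at least 4.13 times as high at passage 30 as at passage 0. That lowest ratio was 2.21 with a limit of 8 UMIs, 7.08 with a limit of 2, 3.62 for cells without a UMI after thinning, 2.11 for cells with fewer than 2 UMIs and 1.41 in all barcodes. With 1 library per state, length of culture cannot be told apart from other differences between cultures, and loss or silencing of the heavy chain gene was not tested.

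The clone B passage 0 library was the second, lying 0.482 and 0.505 from the clone B passage 30 libraries (SD of log2 folds over genes) and nearer, at 0.443 and 0.453, to clone A at passage 30 without glutamine and at passage 0, while the clone A libraries lay 0.244 to 0.267 apart. From clone A at passage 30 with glutamine it lay farther, at 0.521. A swap with the clone A passage 0 library is argued against, since that one lay at most 0.267 from its own passage 30 libraries and at least 0.379 from those of clone B. Depth per cell is argued against as the whole cause, since the smallest distance in thinned cells was 0.50. A library of another line may still be the source and cannot be told apart from a change of clone B in culture, since 61.3% of the genes that differed over 2-fold between the clones in both passage 30 states (46 of 75) kept their sign at passage 0. The comparisons of clone B with passage 0 rest on this library, and that of the clones does in part.

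Lower mitochondrial transcripts with glutamine were the third. Fewer damaged cells could lower all 13 transcripts alike and are argued against as the whole cause, since the SD of their log2 folds was 0.275 in clone A and 0.216 in clone B, with ND2 at −0.77 and ND4L at 0.06 in clone A. Depth per cell is argued against, since in cells of 20000 to 30000 UMIs the median mitochondrial share differed by −0.805 points in clone A and −1.80 points in clone B. A response to glutamine stays open, with 1 library per clone and medium.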

How the results depend on the processing

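Alternatives with cells of at least 10000 UMIs, thinning to 10000 UMIs, library totals, other limits for the heavy-chain-low class, other cells matched on cluster and lists in thinned cells were chosen after seeing the data, and the rest before. Unless a cause is given, the cause was not tested.

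DESeq2 called 44 genes for passage 30 without glutamine against passage 0, 20 for glutamine at passage 30, 94 for passage 30 with glutamine against passage 0 and 1080 for clone A against clone B, where edgeR called 0 each (590, 445, 775 and 2418 at an unadjusted p under 0.05). With edgeR, every culture comparison stayed at 0 under the 11 alternatives that kept all libraries. For the clones the count was 18 with no low-count filter, 2 with a mean of at least 10 CPM, 1 with strict cells, 5 with thinned cells, 4 with G1 cells and 3 without mitochondrial and ribosomal protein genes. It was 69 without the block for culture state, and it stayed at 0 with RLE size factors, all barcodes, doublets removed and cells of at least 10000 UMIs. Leaving out 1 library in turn gave 0 to 1810, 0 to 17, 0 to 2169 and 0 to 3405 genes in the 4 comparisons in the order above, with a lone library then assumed to vary like the others.

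With an estimated correlation camera called 0 lists in each of the 4 comparisons, and fry called 0 in the 3 culture comparisons and 2 between the clones. Of the 13 list calls 1 held with fry and 12 were lost. Between the clones 6 lists passed in G1 cells and 1 in thinned cells. Leaving out 1 library gave 2 to 7 lists for passage 30 without glutamine against passage 0 and 3 to 8 for glutamine. Of the 13 list calls, 13 held with RLE size factors, 11 with thinned cells and 9 with G1 cells. The ribosomal protein list reversed its direction in camera without clone B at passage 0, its medians running from 0.0034 to 0.44 as libraries were left out for passage 30 without glutamine against passage 0. The oxidative stress list reversed for glutamine without clone B at passage 30 without glutamine, with medians of −0.25 to −0.019.

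The correlation of the folds of the clones was 0.35 (0.349) in thinned cells for glutamine, and 0.20 (0.196) with a mean of at least 100 CPM for passage 30 with glutamine against passage 0. Of 287 named folds under 9 alternatives, 1542 of 2565 values were the same within counting error. The sign turned in 5 values, all in G1 cells, whose reported fold lay beyond counting error, and in 15 more, 5 of them with library totals, whose reported fold lay within it. The counting error of the smaller G1 sums was not computed, so a turn to a value near 0 may be noise. The size of low-count folds rests on the pseudocount. Of 281 folds beyond counting error 84 changed in size by over 1.5 times with 10 and 4 with 0.1, by up to 3.09 and 2.61 on the log2 scale, while Fabp4 in clone B stood at −5.82 and −7.57 for passage 30 with glutamine against passage 0. In G1 cells Ddit4 in clone A stood at −0.89 for passage 30 without glutamine against passage 0 and at −0.17 for passage 30 with glutamine against passage 0. Also in G1 cells, the log2 fold of igg_hc, passage 30 with glutamine against passage 30 without glutamine, clone B, was 0.029, the log2 fold of Glul, passage 30 with glutamine against passage 30 without glutamine, clone A, was 0.0063, and Kif20b in clone A stood at 0.25 for passage 30 with glutamine against passage 0.

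The lowest share of a library called G2 or M phase was 77.1% with cells not thinned, 64.7% with each library scored alone and 74.3% when thinned to 10000 UMIs, and the highest was 88.4% not thinned and 86.3% at 10000 UMIs. At a resolution of 1 there were 8 clusters in clone A and 7 in clone B. With a mean of at least 0.5 UMI, 2 of the 30 leading variable genes stayed among the first 5, since fewer genes were then ranked.

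Shares of cells without a heavy chain UMI are given for clone A at passage 0, passage 30 with and passage 30 without glutamine, then clone B in the same order. They were 0.0368, 2.13, 0.481, 0.236, 7.49 and 15.9% not thinned, 1.21, 7.20, 1.71, 0.869, 9.13 and 17.9% in all barcodes, 0 (of 4645 cells), 3.39, 0.588, 0.629, 15.3 and 31.7% thinned to 10000 UMIs, and 1.26, 16.8, 5.54, 15.5, 32.8 and 49.0% with fewer than 2 UMIs. Depth sets these levels, and the order of the libraries within each clone was kept in each of these settings.

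With at most 2 heavy chain UMIs the heavy-chain-low share was 6.93% in clone A with glutamine, 1.27% without, and 3.49% and 24.7% in clone B at passage 0 and with glutamine. With at most 8 it was 0.689, 14.8 and 2.88% in clone A and 13.7 and 30.3% in clone B at passage 0 and with glutamine. In G1 cells it was 7.25 and 0.946% in clone A with and without glutamine, and 7.28 and 27.8% in clone B at passage 0 and with glutamine. Leaving out 1 library gave 7 to 42 genes differing between heavy-chain-low cells and the others, and matching on cluster gave 41.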

Other observations

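All tests of heavy-chain-low cells below and the split of the libraries were chosen after the results were seen.

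Cells with little heavy chain RNA also held less RNA for the folding machinery of the ER, where antibody chains are assembled. Heavy-chain-low cells were compared with the other cells inside each of 4 libraries (clone A with glutamine and the 3 clone B libraries), with counts summed per class and library as a block in edgeR. Herpud1, a gene of ER-associated degradation, had a log2 fold of −0.68 ± 0.04 (SE, adjusted p = 3.63e-05), the ER protein gene Sdf2l1 −0.51 (adjusted p = 0.000189), Dnajc3 −0.34 (0.00281), Pdia6 −0.28 (0.00484), Hyou1 −0.35 (0.00807), Hspa5 −0.31 (0.0113), Hsp90b1 −0.30 (0.0162) and Creld2 −0.47 (0.0200), each lower in 4 of 4 libraries. Translocation genes Sec63 (−0.25), Sec11c (−0.22) and Srpr (−0.24) and the folding enzymes Pdia3 (−0.21) and Ppib (−0.19) were lower as well. These genes were picked for folding or translocation, with no fixed rule. Of the genes called lower, 9 were in the ER chaperone list and 3 in the translocation list. Others called lower included Klhl1 (−0.85), Cfap299 (−0.93), Cdk2ap2 (−0.38), Mrpl23 (−0.45) and Bahcc1 (−0.56). Klhl1 and Cfap299 had a mean of 4.71 and 0.70 CPM. The light chain stood at −2.29, and the heavy chain at −5.05 by construction. Higher in these cells were C1qtnf1 (0.49), Igsf8 (0.35), Ncstn (0.34), Ggh (0.33), the integrins Itgb1 (0.24) and Itgav (0.25), Tmed1 (0.25) and Qsox1 (0.24). Mesd (0.18), Pofut2 (0.23) and Poglut3 (0.25) were among the others called higher.

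Of 11108 genes, 53 were called (23 higher, 30 lower), with 996 at an unadjusted p under 0.05. Without clone B at passage 30 with glutamine 7 genes were called, 23 without clone B at passage 0, 31 without clone A with glutamine and 42 without clone B without glutamine. The ER chaperone list had 20 of 24 members lower, a median of −0.18, and an adjusted p of 9.45e-11 by camera, 0.0159 by fry and 0.254 with an estimated correlation. The translocation list had 22 of 26 lower (adjusted p = 0.000547, and 0.254 with an estimated correlation), and the extracellular matrix list, whose call did not hold below, had 20 of 23 higher (adjusted p = 0.000315, and 0.337 with an estimated correlation). These were not alone, since 15 of 31 lists passed camera (7 lower, 8 higher), 0 with an estimated correlation and 3 with fry, the third being glutamine use, with 18 of 20 members lower (adjusted p = 0.0159 by fry). With the product features left out before scaling 48 genes were called.

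The classes were mixed with clusters in clone B at passage 30, where 61.8% of cluster 1 and 23.6% of cluster 2 were heavy-chain-low without glutamine, and 32.3% and 21.3% with it. The other cells were therefore drawn to the cluster mix of the heavy-chain-low cells in each library. Only cell cycle and histone genes had been left out of the clustering, so product and ER genes could themselves shape the clusters. In clone B at passage 0 the match used 1 cluster and 4593 of 4615 other cells, so it could change little there. The ER list then had 19 of 24 members lower, a median of −0.16 and an adjusted p of 1.55e-09 by camera, 0.0117 by fry and 0.165 with an estimated correlation, and the translocation list had 20 of 26 lower (adjusted p = 0.00157 by camera). Of the 15 camera calls 6 were kept and 9 lost, and of the 3 fry calls 2 were kept. The extracellular matrix call was lost, with 13 of 22 higher, a median of 0.02 in place of 0.10 and an adjusted p of 0.371, as was that of glutamine use, with 12 of 18 lower, a median of −0.03 in place of −0.06 and an adjusted p of 0.181 by fry. With matching 41 genes were called. Of the 53 called before, 39 were kept and 14 lost (10 higher, 4 lower), among them C1qtnf1 (0.39, adjusted p = 0.0539) and Itgav (0.21, adjusted p = 0.0527). Fewer cells were compared, and the effect of that on the calls was not tested. Cluster mix could supply part of the lower ER RNA but is argued against as its whole cause, since the lowest ratio of the matched to the unmatched median over the 4 libraries was 0.758, in clone B without glutamine. That ratio lay just above the bound set for it, with 1 draw of cells, and the clusters themselves changed with the random seed.

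The 10 splits of the 6 libraries into 3 against 3 are too few for a share under 0.05. For clone A against clone B edgeR called 0 genes (2418 at an unadjusted p under 0.05, and 1080 by DESeq2), and the highest of the other splits was 0.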
